A study of Drosophila melanogaster with 12 samples.

How the data were processed

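Whole-animal RNA of adult male Canton-S flies had been hybridized to Affymetrix arrays, 12 in all, in 4 groups of 3 biological replicates per the labels (control or high-sugar diet, 2 days or 4 weeks). According to the series text, the authors extracted probe set values with the perfect match/mismatch model of dChip and normalized them between arrays there. The deposited unit is intensity on a linear scale: the values run from 1, a lower limit that 574 values hold, to 16579.5, and array medians lie close to each other. The reference array, the target level and detection calls are not stated in the labels. Signals near the top of this range change less per fold of RNA on such arrays, so small folds of the brightest genes are less certain.

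Values were read from the deposited table for 18869 probe sets. Values under the pooled 20th percentile (an intensity of 11.78) were set to it and log2 transformed. The 100 control probe sets and the 30% of probe sets with the lowest mean (under log2 4.30) were left out. The annotation supplied for the array gave exactly 1 gene symbol for 13647 probe sets, several for 402 and none for 4720; the last 2 classes were left out of the gene tests and are reported in the closing section. The 13647 probe sets named 11982 genes, and 13544 of them matched the reference gene table by identifier. For genes with several probe sets the one with the highest mean was kept, which left 10418 genes, 975 of them with more than 1 probe set among those tested. Gene positions were not used, because the genome build is not named.

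A model of the 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend; 8 residual and 5 prior degrees of freedom). The 6 contrasts were diet at 2 days, diet at 4 weeks, their difference, their average, and time on each diet. The p-values were adjusted by Benjamini-Hochberg over genes within a contrast, with a threshold of 0.05. An exact test of 3 against 3 arrays on a single gene cannot give a p below 0.1, so no such test was run. Of 39 gene lists (metabolic pathways, immune and stress genes, gene families and tissue markers), 38 had at least 3 members measured. They were tested with limma camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a contrast. The Turandot list had 1 gene measured and was not tested. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

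Named genes followed a rule. For diet at each time and time on control diet it took up to 8 higher and 8 lower genes with the largest log2 fold change among those past the threshold whose groups did not overlap. For the difference, the average and time on high-sugar diet it took up to 5 each way, without the overlap condition for the difference and the average. It added up to 2 higher and 2 lower members per list with the smallest adjusted p, and 12 genes chosen for both diet contrasts whether or not they passed. Of these 12, 8 were tested; Ilp6, Thor, DptA and Hsp22 are not named on the array. The comparisons, tests, lists, naming rule and alternatives were chosen before the data were examined. Exceptions are the tests, genes and gene set stated below to have been chosen or named after results were seen.

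The alternatives were quantile normalization, centring arrays on their medians, floors at the 10th and 30th percentile, no filter or a filter at 50%, eBayes without a trend or with robust estimation, array weights, the replicate number as a block, only the arrays compared, the mean of all probe sets or every probe set, a threshold of 1.5-fold, and leaving out each array. Tissue means, set percentiles and splits of the arrays in the closing section used the same log2 values.

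The fit was tested on simulated data for diet at 2 days, with the 10418 genes, 5 runs and 200 changed genes per run. It recovered 48.1% of genes changed by log2 0.5, 86.6% at 1 and 99.1% at 2; 4.9% of calls were unchanged genes. In a contrast of the same simulated data that held no change it made 0 calls. The share recovered depends on the number of changed genes, since the adjustment is stricter when fewer genes change. The real contrast at 2 days called 15 genes, so the simulated shares may overstate recovery there. Camera called 20 of 20 shifted lists and 0 of 20 unshifted lists at an unadjusted p under 0.05. The simulated genes were drawn independently of each other. The camera result therefore does not show how often lists of genes that move together are called without a shift.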

Results

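Transcript levels were measured on Affymetrix arrays in whole adult male Drosophila melanogaster of the wild-type strain Canton-S. The flies were 3 to 5 days old when they were placed on a control diet or a high-sugar diet. They were fed for 2 days and sacrificed at 5 to 7 days of age, or fed for 4 weeks and sacrificed at 31 to 33 days of age. Each of the 4 groups of diet and time held 3 arrays, which the labels call biological replicates, so 12 arrays in all. The deposited values were linear intensities between 1 and 16579.5, and the median intensity per array ran from 86.97 to 93.42. The number of arrays limits the precision of every comparison, and the median standard error of a log2 fold change between 2 groups was 0.131 over 10418 genes.

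Feeding time (and with it age) separated the arrays more than diet did. The principal component with the largest share held 53.4% of the variance and parted the arrays of 2 days from those of 4 weeks, and the next, with 13.8%, followed diet. Pearson's r between arrays of a group, across genes and therefore not across independent replicates, ran from 0.984 to 0.993. The table gives no scan date or other batch, so a difference between processing days of the 2-day and 4-week arrays cannot be told apart from feeding time.

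**Figure D1:**
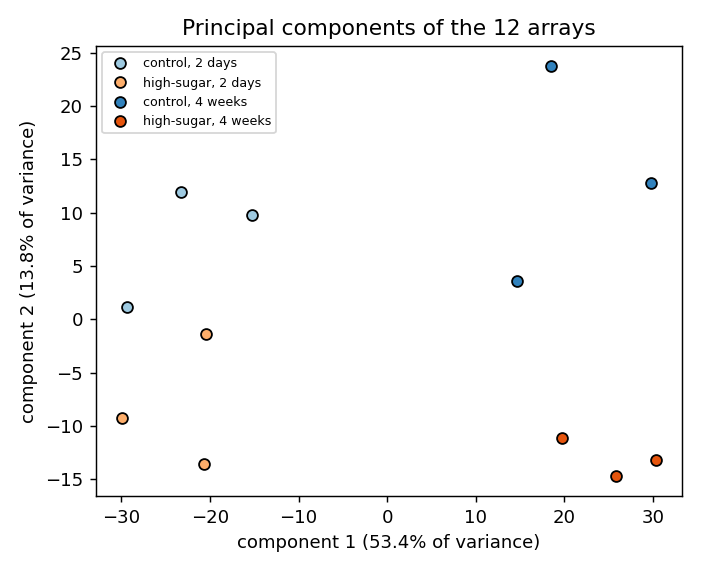
Scores of the 12 arrays on the 2 components that hold the most variance, 53.4% on the horizontal axis and 13.8% on the vertical axis, in log2 units. Each point is an array and each colour a group of 3 arrays; the 2-day and 4-week arrays lie apart on the horizontal axis.

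Diet at 2 days was compared to find the early response to high sugar. Transcripts of a pair of metallothioneins, small proteins that bind metal ions, fell. MtnD (gene 326270) went from a mean intensity of 3470 ± 890 to 591 ± 196 (SD, n = 3 arrays each), a log2 fold change of -2.59 with a standard error of 0.23 and a limma adjusted p of 0.000591. MtnB (gene 42424) went from 356 ± 55.3 to 65.6 ± 16.9 (SD, n = 3 each), with a log2 fold change of -2.46. The arginine methyltransferase gene Art7 (gene 37664) fell by 2.00 on the log2 scale, and the lipase gene Lip3 (gene 41643) had a log2 fold change of -1.55. Smaller falls were measured for CG3604 (-1.18), rtet (-0.83), CG9547 (-0.80), CG31176 (-0.79), the purine synthesis gene Prat2 (-0.58) and the glutathione transferase gene GstE6 (-0.40).

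With these, 15 genes were lower and 0 were higher on high-sugar diet at 2 days by limma at an adjusted p under 0.05, of 10418 tested; 866 had an unadjusted p under 0.05. The remaining 5 of the 15 were CG34040 (-0.69), Shmt (-0.56), SCOT (-0.49), Got2 (-0.36) and CG14292 (-0.28), which fell outside the naming rule and are named after their values were seen. The transcription factor gene sug (sugarbabe, gene 36424) did not pass at 2 days, with a log2 fold change of 1.29, a standard error of 0.34 and a limma adjusted p of 0.251. FASN1 (-0.03), ACC (-0.10), Pepck1 (-0.08), bmm (-0.28), Ilp2 (-0.03) and tobi (-0.17), chosen in advance as genes of fat synthesis and breakdown, sugar metabolism and insulin signalling, did not pass either. The value of Ilp2 changed sign without some arrays, up to 0.09. The yolk protein gene Yp1 stood at the floor in 2 of 3 arrays of each 2-day group, so no fold is given. MtnD passed under every alternative. MtnB and Art7 passed in all but 2, no filter and leaving out high-sugar array 2 at 2 days (adjusted p = 0.0622 without that array), and each of the other 7 named genes lost its call without 4 or more arrays (adjusted p up to 0.185). The count dropped to 5 without control array 1 at 2 days, to 4 without control array 2, to 1 without high-sugar array 2 and to 4 without high-sugar array 3. Leaving out a 4-week array changes the shared spread, the floor and the filter, and their parts were not told apart. The count then became 8 without control array 3 at 4 weeks, 7 without high-sugar array 2 at 4 weeks and 23 without control array 1 at 4 weeks. Quantile normalization left 3, no filter 4, eBayes without a trend 4, while centring on array medians gave 28.

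Among the gene lists fixed in advance, those of sugar digestion, immunity and purine metabolism were called lower on high-sugar diet at 2 days by camera at its preset correlation. None was called with an estimated correlation. Of 10 splits of the 6 arrays, 2 called as many lists as the real one, itself included (12, highest other 12), so these calls do not exclude chance. Of 12 carbohydrate digestion genes (amylases and maltases), 0 passed over all genes while 9 were lower adjusted over the list alone, and the median log2 fold change was -0.37 (limma camera adjusted p = 7.52e-09 at the preset correlation, adjusted p = 0.0851 with an estimated correlation). Of 9 genes of purine synthesis and breakdown, 1 fell and 8 did not pass, with 6 lower adjusted over the list alone and a median of -0.35 (adjusted p = 1.28e-07, adjusted p = 0.0851 with an estimated correlation). Of 22 Toll and Imd pathway members, 0 passed and 10 were lower adjusted over the list alone, with a median of -0.32 (adjusted p = 7.52e-09, adjusted p = 0.317 with an estimated correlation). The 9 antimicrobial peptide genes had a median of -1.47 with 0 past the threshold and 4 lower adjusted over the list alone (adjusted p = 0.00202, adjusted p = 0.329 with an estimated correlation). Their mean log2 intensity differed widely between the control arrays, at 10.18, 9.14 and 7.60, against 7.63, 7.29 and 7.21 on high-sugar diet.

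Camera called 8 further lists at 2 days. They were lipases (1 of 10 fell, median -0.40, adjusted p = 0.329 with an estimated correlation), fatty acid oxidation (1 of 13 fell, median -0.06, 0.003 after quantile normalization, adjusted p = 0.289 with an estimated correlation) and cytochrome P450 enzymes (0 of 51, median -0.09, adjusted p = 0.402 with an estimated correlation). Glutathione S-transferases (1 of 23 fell, median -0.09, estimated adjusted p = 0.329), the pentose phosphate pathway (0 of 5, median -0.18, 0.289), digestive serine proteases (0 of 23, median -0.17, 0.594) and genes of gluconeogenesis, trehalose, glycogen and polyols (0 of 13, median -0.08, 0.413) were also called lower. Sugar-responsive regulators were called higher with 0 of 5 past the threshold and a median of 0.19 (adjusted p = 0.289 with an estimated correlation). Adjusted over the list alone, 3 lipase genes, 3 fatty acid oxidation genes, 2 pentose phosphate genes and 1 gene each of the transferases and proteases were lower, 2 regulators were higher with 1 lower, and of the gluconeogenesis list 1 was higher and 2 lower. With an estimated correlation 0 of 38 lists were called, and fry, which asks only whether the members move one way on balance, called 2. Without 1 array at 2 days the calls of the P450 enzymes (high-sugar array 2, adjusted p = 0.165), the pentose phosphate pathway (control array 2, 0.0872) and the transferases (control array 3, high-sugar array 1 or 2, up to 0.224) were lost. Those of the proteases (control array 1 or 3, high-sugar array 1 or 2, or control array 3 at 4 weeks, up to 0.408), of gluconeogenesis (control array 2 or 3, high-sugar array 1 or 2, or high-sugar array 1 at 4 weeks, up to 0.306) and of the regulators (control array 1 or 3, high-sugar array 1 or 3, or control array 3 at 4 weeks, up to 0.116) were lost too. Quantile normalization kept 8 of the 12 calls and gave 5 lists higher and 7 lower, ending those of the proteases (adjusted p = 0.0666), fatty acid oxidation (0.0791), the pentose phosphate pathway (0.0652) and gluconeogenesis (0.42). Without a trend 8 were kept and 0 lists were higher; the calls of the proteases, the pentose phosphate pathway, gluconeogenesis and the regulators were lost. With no filter or robust estimation those of the proteases and the regulators were lost, and with array weights those of the regulators and gluconeogenesis (up to 0.12).

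Diet at 4 weeks was compared to find the response to long feeding. Transcripts of 3 of 5 sugar-responsive regulators rose, and those of some gut digestive enzymes fell. The activin-like ligand gene daw (dawdle, gene 33474) went from a mean intensity of 202 ± 22 to 575 ± 82.8 (SD, n = 3 each), a log2 fold change of 1.51 with a standard error of 0.14 and a limma adjusted p of 0.000331. The transcription factor gene sug went from a mean intensity of 309 to 1030 (log2 fold change 1.84, standard error 0.34), and cabut (cbt, gene 33224) rose by 0.62. The digestive serine protease gene Jon25Bi (gene 33708) went from 1780 ± 451 to 173 ± 104 (log2 fold change -3.55, standard error 0.59), Lip3 from 433 ± 187 to 67.6 ± 17.6 (-2.63) and the acyl-CoA binding protein gene Acbp3 (gene 38783) from 3040 ± 407 to 705 ± 81.4 (-2.10, limma adjusted p = 2.08e-05).

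In all, 84 genes were higher and 117 lower at 4 weeks by limma, 201 of 10418, and 2069 had an unadjusted p under 0.05. A change of at least 1.5-fold was reached by 52 of the higher and 88 of the lower genes. The largest further rises by the naming rule were those of the cytochrome P450 gene Cyp4e3 (2.09), Iml1 (1.53), a subunit of a complex that restrains TORC1, CngB (1.48), CG13912 (1.27) and the Niemann-Pick type gene Npc2h (1.16). CG12057, at the floor in 2 of 3 control arrays, was at least 7.46-fold higher and is not ranked. The largest further falls were those of PGRP-SC2 (-2.33), an amidase that degrades peptidoglycan, Jon99Ci (-2.31), CG31832 (-2.13), CG15533 (-1.98) and the lipase gene CG6271 (-1.88). Of the genes chosen in advance FASN1 (0.06), ACC (-0.08), Pepck1 (0.06), bmm (-0.25), Ilp2 (0.16), tobi (-0.24) and Yp1 (-0.65) did not pass. Of 39 named genes that passed, 14 did so under every alternative: Iml1, daw, CG13912, Npc2h, Lip3, PGRP-SC2, Acbp3, CG6271, Amyrel, epsilonTry, CG8093, CG9547, cbt and ry. The call of sug was lost without control array 3, high-sugar array 1 or high-sugar array 2 at 4 weeks (adjusted p up to 0.0732), and that of Jon25Bi with no filter (0.051). With no filter 21 of the 39 lost their calls, sug among them (0.0698). Those of CG12057 (control array 3, high-sugar array 1 or 2, up to 0.0923), CngB (control array 3 or high-sugar array 2, up to 0.0809) and CG31832 (control array 3, 0.0588) were lost without 1 array of 4 weeks. Cyp4e3, CG15533 and Jon99Ci lost theirs without 5 or more arrays (up to 0.17, 0.111 and 0.127). The count dropped to 88 without control array 3, to 82 without high-sugar array 2 and to 96 without high-sugar array 3 at 4 weeks, to 119 with no filter and to 127 with only the 6 arrays compared. The higher genes alone numbered 28, 38, 30 and 37 without control array 3 or high-sugar array 1, 2 or 3 at 4 weeks (lower 60, 110, 52 and 59), and 142 without control array 2 at 4 weeks.

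**Figure D2:**
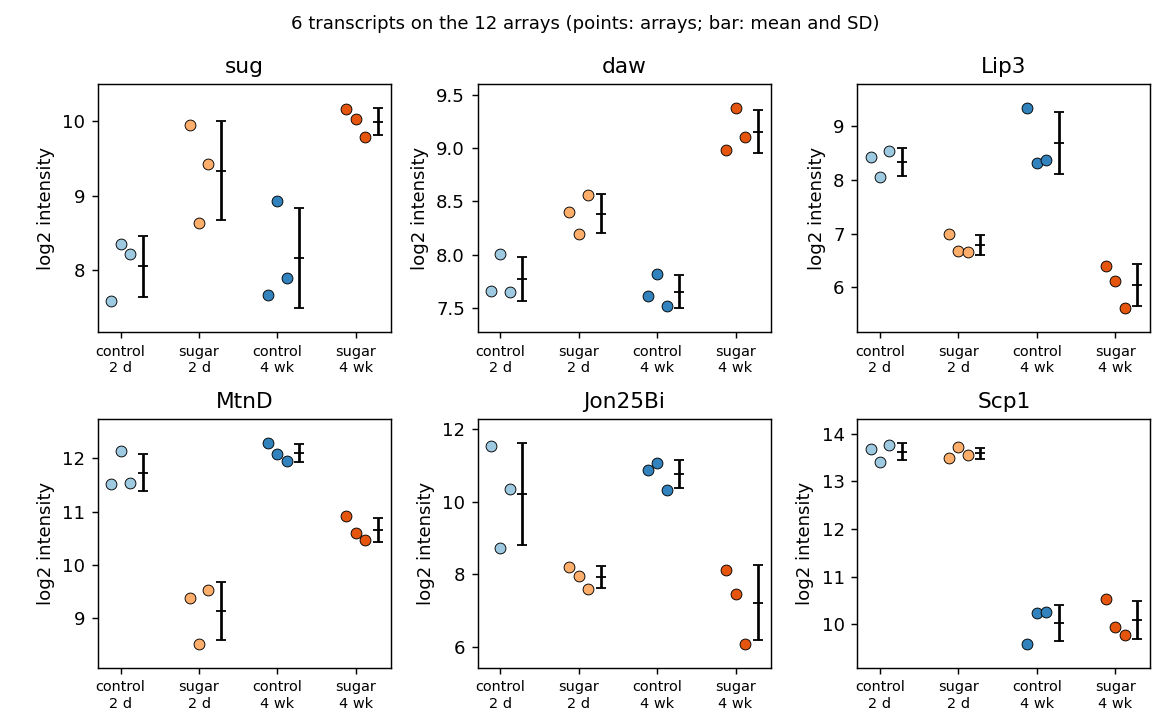
Log2 intensity of sug, daw, Lip3, MtnD, Jon25Bi and Scp1 on the 12 arrays, with 3 points per group and a bar for the mean and SD. In the panel of daw the 3 high-sugar arrays lie above the 3 control arrays at both times; in that of Scp1 the 6 arrays of 4 weeks lie below the 6 of 2 days.

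Some genes for digesting proteins, sugars and lipids were lower on high-sugar diet at 4 weeks. Of 23 digestive serine protease genes, 4 fell and 0 rose, among them epsilonTry (-1.35), and 13 were lower and 1 higher adjusted over the list alone. The median was -0.39 (camera adjusted p = 1.04e-07, adjusted p = 0.274 with an estimated correlation). Of 12 carbohydrate digestion genes 2 fell, Amyrel (-1.44) and the maltase gene Mal-A4 (-0.99), with 8 lower adjusted over the list alone and a median of -0.28 (adjusted p = 2.25e-05, adjusted p = 0.274 with an estimated correlation). Of 10 lipase genes 3 fell, among them Lip3 and CG8093 (-1.59); 5 were lower and 2 higher adjusted over the list alone, with a median of -0.34 (adjusted p = 0.00716, adjusted p = 0.383 with an estimated correlation, lost with no filter). The call of Mal-A4 was lost without any 1 of the 6 arrays of 4 weeks (adjusted p up to 0.0935). In the same arrays the testis list was lower and the neuron, photoreceptor and muscle lists higher, with medians of -0.17, 0.33, 0.31 and 0.17 (adjusted p = 0.383, 0.274, 0.274 and 0.48 with an estimated correlation).

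Some regulators of the sugar response rose at 4 weeks and some genes of purine metabolism fell. Of 5 sugar-responsive regulators 3 rose (sug, daw and cbt), as many adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.000282, adjusted p = 0.119 with an estimated correlation). Of 9 purine genes 3 fell, among them the xanthine dehydrogenase gene ry (-0.65) and Gart (-1.20), with 4 lower adjusted over the list alone and a median of -0.15 (adjusted p = 0.00359, adjusted p = 0.274 with an estimated correlation). Of 17 genes of lipogenesis and fat storage 2 rose, FASN2 (0.78) and the perilipin gene Lsd-2 (0.33), 3 adjusted over the list alone, and the list was not called (median 0.05, adjusted p = 0.215). Of 13 genes of gluconeogenesis, trehalose, glycogen and polyols Pepck2 rose (0.79) and Sodh1 fell (-0.46), 1 and 2 adjusted over the list alone, with the list not called (adjusted p = 0.36). The sugar transporter gene SLC5A11 rose by 0.48, 1 of 8 in its list. The call of Sodh1 was lost with only the 6 arrays compared (adjusted p = 0.0612). Leaving out 1 array at 4 weeks ended the calls of Gart (control array 3 or high-sugar array 2, adjusted p up to 0.0522), Pepck2 (high-sugar array 2, 0.0506), FASN2 (any high-sugar array, up to 0.0938) and SLC5A11 (control array 1 or 3, high-sugar array 1 or 3, up to 0.0976). The call of Lsd-2 was lost without control array 1 or 3 or any high-sugar array at 4 weeks, or control array 3 or high-sugar array 2 at 2 days (up to 0.131).

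Markers of other tissues differed between the diets at 4 weeks in opposite directions. Of 24 testis genes 0 passed, also adjusted over the list alone, and 23 had a negative value, with a median of -0.17 (camera adjusted p = 5.36e-06, adjusted p = 0.383 with an estimated correlation). Of 13 neuronal genes synapsin (Syn, 0.57) rose, 9 rose adjusted over the list alone and 13 had a positive value, with a median of 0.33 (adjusted p = 1.34e-05, adjusted p = 0.274 with an estimated correlation). Of 13 photoreceptor genes the phototransduction scaffold gene inaD (0.45) rose, 6 adjusted over the list alone, with a median of 0.31 (adjusted p = 0.000108, adjusted p = 0.274 with an estimated correlation). Of 21 muscle genes 0 passed by either adjustment and 20 were positive (median 0.17, adjusted p = 0.00359, adjusted p = 0.48 with an estimated correlation), a call lost without control array 3 at 4 weeks (0.0828). Basement membrane and matrix genes had a median of 0.23 with 0 of 10 past the threshold and 1 higher adjusted over the list alone (adjusted p = 0.00372, adjusted p = 0.274 with an estimated correlation). The call of inaD was lost without control array 3, high-sugar array 2 or high-sugar array 3 at 4 weeks (adjusted p up to 0.118). That of Syn was lost without control array 3 or any high-sugar array at 4 weeks, or control array 3 or high-sugar array 2 at 2 days (up to 0.13).

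Immune and detoxification genes at 4 weeks gave weaker list results. Of 22 Toll and Imd members PGRP-SC2 and pirk (-1.62), a repressor of Imd signalling, fell, with 3 lower and 1 higher adjusted over the list alone, and the list was not called (adjusted p = 0.327). Of 51 cytochrome P450 genes 1 rose and 3 fell (median -0.09, camera adjusted p = 0.0323, adjusted p = 0.539 with an estimated correlation), and 2 rose and 8 fell adjusted over the list alone. Of 23 glutathione S-transferase genes 1 fell, GstD5 (-1.09), with 4 lower and 1 higher adjusted over the list alone (median -0.08, adjusted p = 0.0485, adjusted p = 0.472 with an estimated correlation). The 9 antimicrobial peptide genes had a median of -0.85 with 0 past the threshold by either adjustment (adjusted p = 0.0485, adjusted p = 0.48 with an estimated correlation). Leaving out 1 array ended the calls of the P450 list (control array 2 or high-sugar array 3 at 4 weeks, adjusted p up to 0.102), the transferase list (control array 2 or high-sugar array 1 or 3 at 2 days, control array 1 or 2 or high-sugar array 1 at 4 weeks, up to 0.27) and the peptide list (control array 2 or any high-sugar array at 2 days, control array 1 or 3 or high-sugar array 3 at 4 weeks, up to 0.13). Of the other alternatives 4 ended the transferase call and 6 the peptide call (up to 0.1 and 0.145). The calls of pirk (without control array 3 or high-sugar array 2 at 4 weeks, up to 0.071) and GstD5 (without control array 1 or 3 or high-sugar array 2, up to 0.0809) were lost too. Outside the called lists Obp56a fell by 1.39, a call lost without control array 3 at 4 weeks (0.0511) and with no filter; Obp18a (0.49), Alp4 (0.48) and Lsp2 (-1.13) passed but lost their calls without 4 or more arrays (up to 0.172). With an estimated correlation 0 of 38 lists were called at 4 weeks, against 13 at the preset correlation and 10 with fry.

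**Figure D3:**
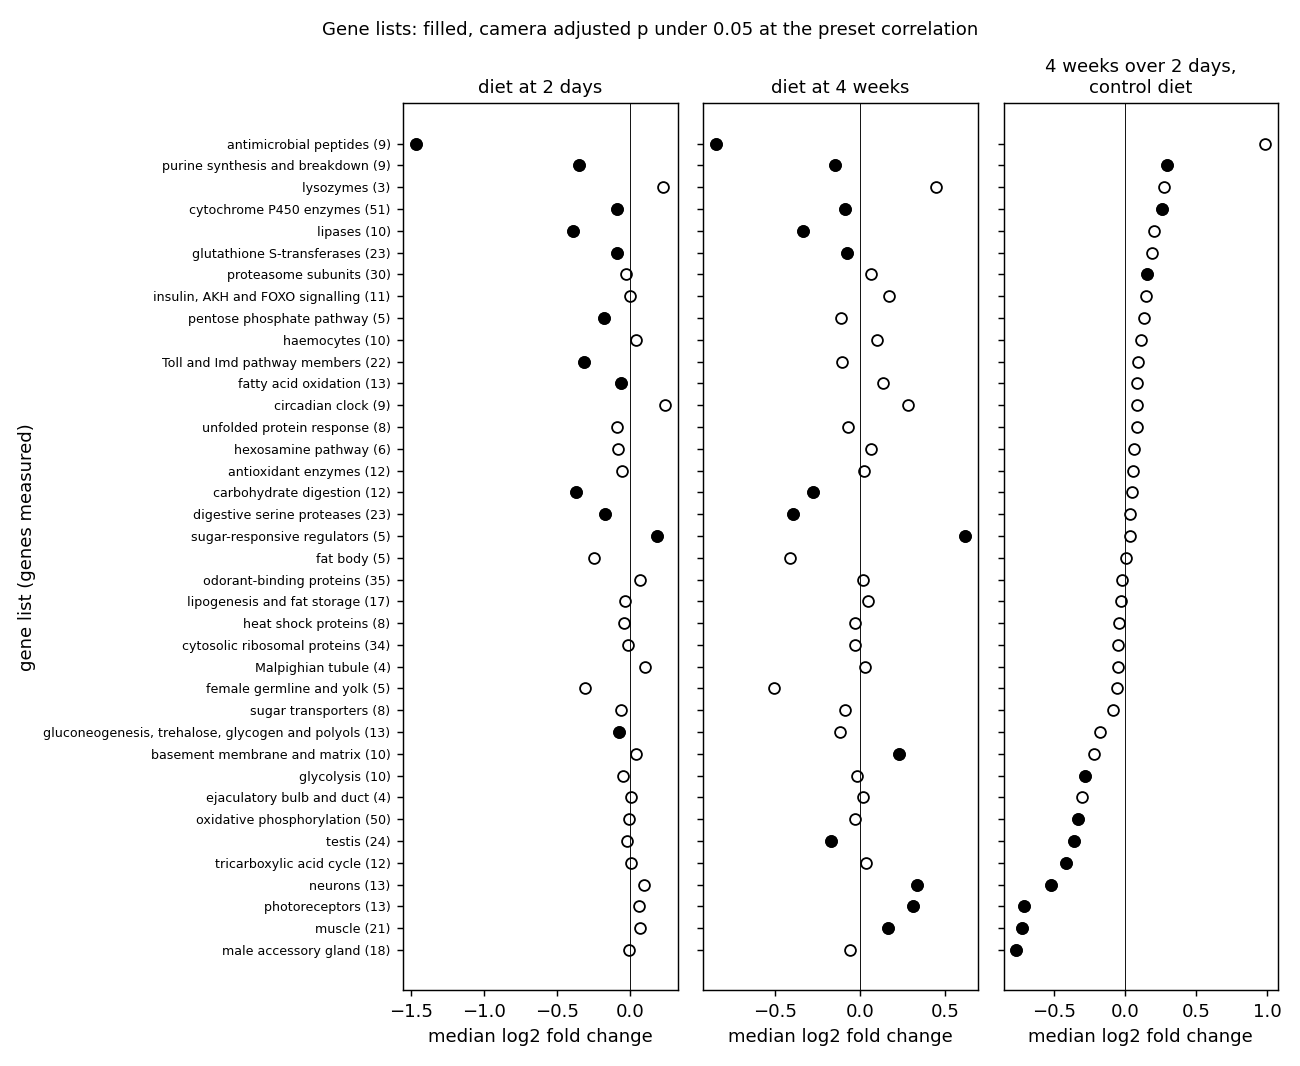
Median log2 fold change of the 38 lists tested, for diet at 2 days, diet at 4 weeks and feeding time on control diet, with filled points for a camera adjusted p under 0.05 at the preset correlation and the number of genes measured in brackets. Carbohydrate digestion lies at -0.37 and -0.28 in the panels of diet; muscle lies at -0.73 in that of time. The direction of fatty acid oxidation at 2 days flips to 0.003 after quantile normalization.

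The diet effects at 2 days and 4 weeks, which share no array, were set side by side to ask whether the early response persisted. MtnD, Lip3, CG9547, CG34040, Prat2, SCOT, Shmt and Got2 were lower at both times, 8 genes where 0.168 were expected from independent lists. The lists were not independent, since each gene's variance came from all 12 arrays and genes move together, so 0.168 is not the value without a shared effect. Across 10418 genes, which are not independent, Pearson's r of the effects was 0.42 and Spearman's rho 0.316. Of the 201 genes past the threshold at 4 weeks, 182 (90.5%) had a value of the same sign at 2 days, against 61.2% of all 10418 genes. A limma test of the difference between the diet effects called 0 genes, with a smallest adjusted p of 0.0962 and 757 genes at an unadjusted p under 0.05. No gene was thus shown to respond differently at the 2 times. Without control array 2 or high-sugar array 2 at 2 days or control array 3 at 4 weeks 1 gene passed, without control array 2 at 4 weeks 3, and with no filter 1.

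**Figure D4:**
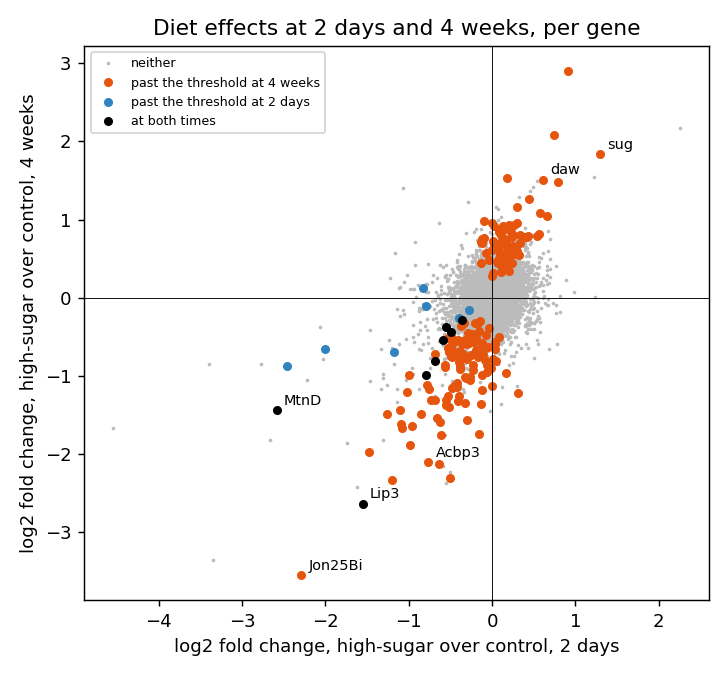
Log2 fold change of high-sugar over control diet per gene, at 2 days on the horizontal and at 4 weeks on the vertical axis. Black points are the 8 genes past the threshold at both times, all lower at both, and coloured points passed at 1 time.

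Averaged over both times, with 6 arrays per diet, 93 genes were higher and 180 lower by limma. The largest rises were those of CG12374 (2.21), sug (1.57, standard error 0.24), Cyp4e3 (1.42) and CG3348 (1.38); CG12057, at the floor in 1 control array of 2 days and 2 of 4 weeks, was at least 3.74-fold higher. The largest falls were those of Jon25Bi (-2.92, standard error 0.42), Lip3 (-2.09), Jon25Bii (-2.03), MtnD (-2.02) and PGRP-SC2 (-1.77). Of 12 carbohydrate digestion genes 7 fell and of 9 purine genes 5 fell, with 10 and 5 adjusted over the lists alone (camera adjusted p = 9.61e-08 and 3.15e-05, adjusted p = 0.106 and 0.157 with an estimated correlation). Of these 10 named genes 5 passed under every alternative, while CG12057 lost its call without high-sugar array 3 at 2 days, control array 3 or high-sugar array 2 at 4 weeks (adjusted p up to 0.0661), and Jon25Bii and Cyp4e3 lost theirs without 6 and 8 arrays (up to 0.0754 and 0.11). With no filter the calls of CG12374 (0.0591), CG12057 (0.0795), Cyp4e3 (0.117), CG3348 (0.0667) and Jon25Bii (0.0919) were lost, and robust estimation ended the same 5. Camera called 16 lists at the preset correlation and 0 with an estimated correlation. Among the 16 were the neuron, photoreceptor and muscle lists (higher) and the testis and fat body lists (lower). The count was 165 without high-sugar array 3 at 2 days, 150 without high-sugar array 2 at 4 weeks, 175 without high-sugar array 3 at 4 weeks and 178 with no filter. The higher genes alone numbered 55, 56, 58 and 44 without control array 1 or 2 or high-sugar array 1 or 3 at 2 days, 61, 53, 39 and 48 without control array 3 or high-sugar array 1, 2 or 3 at 4 weeks, and 158 without control array 2 at 4 weeks. The lower genes fell to 111 without high-sugar array 2 at 4 weeks.

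Time on the control diet was compared between 2 days and 4 weeks, a span over which the flies also aged. Some muscle, eye and male reproductive transcripts fell. Scp1 (gene 3355102), a sarcoplasmic calcium-binding protein, went from a mean intensity of 12700 to 1070 (n = 3 arrays each), a log2 fold change of -3.60 with a standard error of 0.20 and a limma adjusted p of 4.05e-07. Other large falls were those of CG7203 (-3.50), fit (-3.43), the corneal protein gene retinin (-3.24), the troponin C gene TpnC4 (-3.14), CG7214 (-2.91), the accessory gland gene Acp53C14c (-2.89) and the neuropeptide-like gene Nplp3 (-2.76). The largest rises were those of CG10814 (3.37, standard error 0.26), the cuticle protein gene Cpr67Fb (2.75), CG18557 (2.5), the antibacterial protein gene Listericin (2.27, standard error 0.51) and CG4269 (2.20). Yp1, Diedel and CG15239, at the floor in 2, 1 and 3 of 3 arrays of 2 days, were at least 5.95-fold, 5.82-fold and 5.81-fold higher at 4 weeks and are not ranked.

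By limma 1488 genes were higher and 1961 lower at 4 weeks on control diet, 33.1% of 10418. After quantile normalization 1893 were higher and 1830 lower, so which direction held more genes depended on the scaling. Of 106 named genes 74 passed under every alternative. The count dropped to 2139 without control array 3 at 2 days and to 2153 without control array 1 at 4 weeks, the higher genes alone to 809 and 831 and, without control array 1 at 2 days, to 940, and 1369 genes changed by at least 1.5-fold.

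Energy metabolism and muscle lists were lower at 4 weeks on the control diet. Of 50 oxidative phosphorylation genes 44 fell, 1 rose and 5 did not pass, with the same numbers adjusted over the list alone and a median of -0.33 (camera adjusted p = 3.24e-17, adjusted p = 0.21 with an estimated correlation). Examples were ATPsynB (-0.42, standard error 0.05) and UQCR-14 (-0.48), while UQCR-11 rose by 1.62. Of 21 muscle genes 18 fell and 0 rose, by either adjustment, among them the troponin C gene TpnC41C (-2.41) and the actin gene Act79B (-1.55), with a median of -0.73 (adjusted p = 1.23e-11, adjusted p = 0.21 with an estimated correlation). Of 12 genes in the list of the tricarboxylic acid cycle 10 fell, by either adjustment, such as mAcon1 (-0.48), with a median of -0.42 (adjusted p = 2.61e-06, adjusted p = 0.21 with an estimated correlation). Of 10 glycolytic genes 7 fell, such as Gapdh1 (-0.57) and Pfk (-0.68), and 8 adjusted over the list alone, with a median of -0.28 (adjusted p = 0.000103, adjusted p = 0.0859 with an estimated correlation). The glycogen phosphorylase gene Glyp fell by 1.19.

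Lists of the accessory gland, testis, eye and neurons were lower in the same comparison. The list of the ejaculatory bulb and duct was not called (camera adjusted p = 0.153). Of 18 accessory gland genes 15 fell and 1 rose, with 16 and 1 adjusted over the list alone and a median of -0.77 (camera adjusted p = 1.93e-09, adjusted p = 0.392 with an estimated correlation). They included Acp62F (-1.46) and the sex peptide gene SP (-0.81), while Acp26Ab rose by 0.51. Of 24 testis genes 16 fell and 1 rose, with 17 and 1 adjusted over the list alone (median -0.36, adjusted p = 6.21e-06, adjusted p = 0.436 with an estimated correlation); ocn (-0.62) and Mst84Db (-0.50) fell and mia (0.93) rose. Of 13 photoreceptor genes 9 fell by either adjustment, such as Gbeta76C (-1.18) and chaoptin (chp, -1.08), with a median of -0.71 (adjusted p = 6.21e-06, adjusted p = 0.21 with an estimated correlation). Of 13 neuronal genes 7 fell by either adjustment, such as the glutamate decarboxylase gene Gad1 (-1.04) and the GABA receptor gene Rdl (-0.89), with a median of -0.52 (adjusted p = 0.00267, adjusted p = 0.436 with an estimated correlation).

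Cytochrome P450, proteasome and purine lists were higher at 4 weeks on the control diet. Of 51 cytochrome P450 genes 22 rose and 2 fell, with 24 and 2 adjusted over the list alone and a median of 0.26 (camera adjusted p = 0.000175, adjusted p = 0.406 with an estimated correlation), among them Cyp309a1 (1.16). Of 30 proteasome genes 9 rose and 3 fell, with 10 and 3 adjusted over the list alone (median 0.16, adjusted p = 0.00759, adjusted p = 0.744 with an estimated correlation); Prosbeta5 (0.42) rose and Rpn12R (-0.58) fell. Of 9 purine genes 6 rose by either adjustment, such as AMPdeam (0.39), with a median of 0.29 (adjusted p = 0.00832, adjusted p = 0.392 with an estimated correlation). The glutathione S-transferase list was not called, with 6 of 23 genes higher and 1 lower by either adjustment (adjusted p = 0.132). In other lists that were not called, the antimicrobial peptide gene CecB (1.87), pirk (1.5), Akt (0.78) and sut2 (0.83) rose, and the prophenoloxidase gene PPO2 (-1.65), the collagen gene Col4a1 (-0.94) and the insulin-like peptide gene Ilp5 (-0.87) fell. The call of CecB was lost without control array 3 at 2 days (adjusted p up to 0.0566). With an estimated correlation 0 lists were called against 11 at the preset correlation.

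Time on the high-sugar diet gave 2068 higher and 2370 lower genes by limma, 42.6% of those tested, and after quantile normalization 2452 were higher and 2288 lower, so here too the balance depended on the scaling. Genes of antimicrobial proteins were among the largest rises, DptB by 4.77 on the log2 scale (standard error 1.36), Mtk by 3.55, Def by 3.07 and Listericin by 2.88, and Cyp4e3 rose by 2.88. Of 9 antimicrobial peptide genes 4 rose and 2 fell, by either adjustment, and the list was not called (camera adjusted p = 0.339). Their mean log2 intensity on high-sugar diet went from 7.38 ± 0.22 at 2 days to 8.90 ± 0.14 at 4 weeks (SD, n = 3 arrays each). On control diet it was 8.97 ± 1.30 and 9.89 ± 1.03, so the rise on high-sugar diet began from a low mean and did not exceed the control means. The largest falls were those of fit (-3.85), Scp1 (-3.50), Acp53C14c (-3.27), CG7203 (-3.26) and TpnC4 (-3.14). The calls of DptB without high-sugar array 3 at 4 weeks, of Mtk without high-sugar array 2 or 3 at 2 days or any high-sugar array at 4 weeks, and of Def without high-sugar array 2 at 2 days were lost (adjusted p up to 0.0548, 0.11 and 0.0525). Across genes, Pearson's r between the time effects on the 2 diets was 0.826, with no array shared; 1056 genes rose on both diets (295 expected from independent lists), 1554 fell on both (446 expected) and 2 moved in opposite directions. These lists shared each gene's variance too.

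Of 50 oxidative phosphorylation genes 42 fell and 1 rose on the high-sugar diet, of 24 testis genes 20 fell, and of 21 muscle genes 17 fell. Adjusted over the lists alone the falls were 43, 21 and 17, with medians of -0.37, -0.52 and -0.57 (camera adjusted p = 5.87e-15, 1.13e-08 and 1.54e-08, and adjusted p = 0.281, 0.288 and 0.281 with an estimated correlation). Of 30 proteasome genes 17 rose and 3 fell, of 22 Toll and Imd members 9 rose, and of 13 fatty acid oxidation genes 7 rose. Adjusted over the lists alone 19, 9 and 7 rose, with medians of 0.27, 0.38 and 0.24 (adjusted p = 0.00102, 0.00324 and 0.004, and adjusted p = 0.633, 0.633 and 0.281 with an estimated correlation). The high-sugar arrays of 2 days also enter diet at 2 days, with opposite sign. The rises of the Toll and Imd and fatty acid oxidation lists are therefore not independent of their lower values there. On control diet 3 of 22 and 2 of 13 of their genes rose with time, and neither list was called (camera adjusted p = 0.258 for both). The other 7 of 13 called lists were accessory gland (16 of 18 fell, 2 rose), tricarboxylic acid cycle (8 of 12 fell), glycolysis (8 of 10 fell), photoreceptors (8 of 13 fell), cytochrome P450 enzymes (20 of 51 rose), purine genes (7 of 9 rose) and sugar-responsive regulators (4 of 5 rose), with adjusted p from 0.135 to 0.398 with an estimated correlation. Adjusted over the lists alone these numbers were the same except for the tricarboxylic acid cycle, with 9.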

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

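Of the tests in this part, the MtnD to MtnB ratio, the comparison of neuron and accessory gland lists, that of muscle with other tissue lists and the size of r over splits were chosen only after the result was seen, as was leaving out members of the metal-response set; the patterns themselves were found in these data.

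A test of the difference between the diet effects (4 weeks minus 2 days) called 7 lists with camera at its preset correlation and 0 genes. The median log2 differences were -0.266 for digestive serine proteases, -0.151 for testis, 0.202 for photoreceptors, 0.219 for neurons, 0.233 for fatty acid oxidation, 0.255 for Toll and Imd members and 0.431 for sugar-responsive regulators. With an estimated correlation 0 lists were called (adjusted p from 0.288 for the regulators to 0.825 for Toll and Imd members), and fry called 0. Without control array 1 at 4 weeks 11 lists were called. The Toll and Imd call was lost without control array 1 at 2 days or control array 2 at 4 weeks (adjusted p up to 0.303), and the neuron call without control array 3 or high-sugar array 1 at 2 days or control array 3 at 4 weeks (up to 0.119). Of 100 splits of the arrays within each time, 53 called as many lists as the real one (7, highest other 20), so chance is not excluded.

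Probe sets without exactly 1 gene, which the gene tests did not use, also passed the threshold when every probe set was tested. Of 1786 such probe sets, 2 passed for diet at 2 days, 21 for diet at 4 weeks (7 higher, 14 lower) and 480 for time on control diet (234 higher, 246 lower).

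MtnB and MtnD, of 4 metallothionein genes tested, were lower on high-sugar diet in the average over both times, while MtnA (-0.03, adjusted p = 0.832) and MtnC (-0.64, adjusted p = 0.0635) did not pass. Leaving out any 1 array kept at least 88.7% of the averaged log2 fold change of MtnB or MtnD, which argues against 1 array as the source. Whether both probe sets read 1 signal stays open, since the MtnD to MtnB ratio differed between groups (permutation p = 0.021) mainly with feeding time, with log2 means on control and high-sugar diet of 3.27 ± 0.14 and 3.14 ± 0.14 at 2 days and 4.21 ± 0.32 and 3.65 ± 0.51 at 4 weeks (SD, n = 3 arrays each), and between the diets within the times an exact test gave p = 0.21. Lower activity of the metal-responsive factor MTF-1 stays open. The other 4 measured genes under its control (MtnA, MtnC, ZnT35C and CG10505) had a mean averaged log2 fold change of -0.27. This lay at percentile 2.19 of 10000 random sets of like brightness, which met the bound of 2.5 set in advance. Leaving out members, a condition added after that result, gave 1.42 without MtnA, 2.46 without ZnT35C and 2.13 without CG10505, but 12.7 without MtnC. The set thus depends on MtnC, and MtnA lies near the top of the intensity range. An effect of the diet itself, its metal content included, stays open and was not tested.

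The testis list was lower and the neuron, photoreceptor and muscle lists higher on high-sugar diet at 4 weeks (adjusted p = 0.383, 0.274, 0.274 and 0.48 with an estimated correlation). Each list kept at least 77.5% of its median without any 1 of the 6 arrays (muscle 159% without control array 2, testis 145% without high-sugar array 1). This argues against 1 array as the whole cause. Each kept at least 87.1% after quantile normalization. The deposited values were already normalized between arrays, so this further step cannot test the normalization by the authors. A lower share of testis RNA alone would raise other tissues alike. Yet the mean of the neuron list exceeded that of the accessory gland list by 0.38 (standard error 0.06). This error is over list members, which move together (estimated correlation 0.305 for neurons and 0.545 for accessory gland). It does not measure the spread between arrays, so the difference does not decide this point. This comparison and that of time on control diet share the control arrays of 4 weeks, with opposite sign, so their list results are not independent. The medians with time of the neuron, photoreceptor, muscle and testis lists were -0.52, -0.71, -0.73 and -0.36 on control diet. On high-sugar diet they were -0.16, -0.37, -0.57 and -0.52. An effect of diet on the relative amounts of these tissues, or on their transcripts, may underlie the pattern. These data do not decide that hypothesis, and arrays of dissected tissues would test it. The number of lists called at 4 weeks was 13, with a highest other of 13 among 10 splits, which are too few for a share under 0.05.

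The oxidative phosphorylation and muscle lists were lower at 4 weeks on control diet (adjusted p = 0.21 for both with an estimated correlation). The median of the former lay at percentile 0 of 10000 random lists of like brightness, whose median was -0.06 and whose central 95% ran from -0.13 to 0.01. This argues against a lower reading of bright probe sets as a class as the whole cause for that list. The muscle list was not tested in this way. Both lists kept at least 92% of their median without any 1 array, which argues against 1 array as the cause. A smaller share of muscle RNA alone would raise other tissues. Yet the testis, neuron, photoreceptor and accessory gland lists fell too, with means of -0.32, -0.43, -0.60 and -0.91 (standard errors 0.06, 0.11, 0.11 and 0.20). These errors are over list members, which move together, and do not measure the spread between arrays. The lists had been called lower before this comparison was chosen. With an estimated correlation none of them passed (camera adjusted p = 0.436, 0.436, 0.21 and 0.392 in the same order). The comparison thus does not decide whether a smaller share of muscle RNA alone underlies the pattern. Age stays among the open explanations, and a difference between processing days was not tested because the labels give none.

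Splits of the arrays were also counted for each result. Of 10 splits of 6 arrays, too few for a share under 0.05, 1 gave as many genes as the real one for diet at 2 days (15, highest other 0), diet at 4 weeks (201, highest other 3), time on control diet (3449, highest other 3) and time on high-sugar diet (4438, highest other 0). For lists the splits as large were 2 at 2 days (12, highest other 12), 2 at 4 weeks (13, highest other 13), 4 for time on control diet (11, highest other 11) and 3 for time on high-sugar diet (13, highest other 17). Over 100 of the 200 splits within each time, only the real one gave as many as the 273 genes of the averaged diet effect (highest other 113). This argues against chance for that number. The sign of the r of 0.42 between the diet effects depends on which side of a split is named high-sugar. Its size was therefore compared over all 100 splits with mirrors taken once, and 2 were as large, the real one included (highest other 0.451). Chance is thus unlikely for this r but not excluded, and the measure was chosen after the result was seen. Over the 100 drawn splits chance is not excluded for the 16 lists of the averaged effect (5 splits, highest other 18). For the difference between the diet effects the real number of genes was 0, so all 100 splits gave as many by construction (highest other 12) and this says nothing about chance.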

How the results depend on the processing

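No test in this part was chosen after the result was seen. Of 175 named gene results past the threshold, 101 stayed past it in the same direction under every alternative and 74 did not. Of 72 list calls, 56 held in every alternative but the 2 other set tests and 44 held with fry; with an estimated correlation 0 lists were called in each of the 6 contrasts, while fry called 2 for diet at 2 days, 0 for the difference between the diet effects and 21 for time on high-sugar diet. The 15 genes of diet at 2 days became 3 after quantile normalization, 28 after centring on medians, 4 with no filter, 23 with the lowest 50% left out, 4 without a trend, 26 with robust estimation, 27 with array weights and 9 at 1.5-fold. With no filter, diet at 4 weeks gave 119 genes, the difference 1, the average 178 and the correlation 0.384; the correlation was 0.488 with the lowest 50% left out. No filter tests more genes; the cause was not tested for the other changes. With only the arrays compared, which leaves fewer arrays, diet at 4 weeks gave 127 genes. At 1.5-fold the average gave 97 genes, time on control diet 1369 and time on high-sugar diet 1934. Leaving out 1 array gave 1 to 23 genes for diet at 2 days, 82 to 2.6e+02 (to 2 significant digits) at 4 weeks, 0 to 3 for the difference, 150 to 376 for the average, 2139 to 3512 and 3288 to 4628 for time on control and high-sugar diet, and a correlation of 0.34 to 0.436. Lists called then numbered 8 to 13 at 2 days, 11 to 17 at 4 weeks and 6 to 11 for the difference. Results that changed sign were CG8036 for time on control diet (0.067 after quantile normalization), the fatty acid oxidation list at 2 days (0.003 after quantile normalization), and at 2 days without 1 array Ilp2 (-0.111 to 0.092) and Yp1 (-0.201 to 0.083); the cause was not tested.

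With the replicate number as a replicate block, diet at 2 days gave 10 genes and diet at 4 weeks 134, the average 213 and time 3165 on control and 4185 on high-sugar diet. The arrays share only a number: of 18 pairs of residual profiles with the same number, 4 had an r over 0.1, in a range of -0.228 to 0.147, and the own number was best in 5. Of 10418 genes 1219 had a mean below 46.6, the 95th percentile of the 100 control probe sets, whose median was 8.38. Whether these control probe sets measure background was not tested, so this is only a rough mark of dim genes, whose values are less certain.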

Other observations

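The set of one-carbon genes in this part was chosen after its values were seen, and it tests no hypothesis.

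Some genes of the folate and methionine cycles were lower on high-sugar diet. Of 16 in a set that had no enrichment test, 8 fell and 0 rose by limma in the average over both times, and 14 had a negative value. The glycine cleavage gene CG3999 (-1.38, standard error 0.22), the folate enzyme gene Nmdmc (-1.14, standard error 0.18), the sarcosine dehydrogenase gene Sardh (-0.96), pug (-0.56), the adenosylhomocysteinase gene Ahcy (-0.55), Cth (-0.52), Gnmt (-0.51) and Shmt (-0.46) passed. By time, 1 of 16 fell at 2 days and 5 of 16 at 4 weeks. In the same average the fat body list was lower, with 1 of 5 genes past the threshold, 3 adjusted over the list alone and a median of -0.33 (camera adjusted p = 0.0448, adjusted p = 0.244 with an estimated correlation), a call lost on leaving out any 1 of 6 of the 12 arrays (adjusted p up to 0.0792) and with 5 of the other alternatives (up to 0.14).

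The mean of 9 antimicrobial peptide genes varied more between control arrays than between high-sugar arrays of the same time. This mean log2 intensity was 8.97 ± 1.30 on control and 7.38 ± 0.22 on high-sugar diet at 2 days, and 9.89 ± 1.03 and 8.90 ± 0.14 at 4 weeks (SD, n = 3 arrays each). The mean hides its members, since among the high-sugar arrays of 4 weeks DptB ran from 8.46 to 11.02, and Drsl4 from 9.71 to 11.85 against 10.67 to 11.81 on control diet. The difference in spread was not tested.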
